A study of Homo sapiens with 2 samples.

How the data were processed

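Expression was measured in SUM149PT, a human cell line derived from an inflammatory breast cancer, on Affymetrix whole-transcript microarrays. An array of this kind reports, for each probe set, the brightness of biotin-labelled fragments made from the RNA of many cells. Per the labels' protocols, the cells grew in an equal mix of DMEM and Ham's F-12 with 5% serum, hydrocortisone at 1 µg/ml and insulin at 5 µg/ml, and 100 to 150 ng of total RNA extracted on silica columns went into each labelling. Of the 2 arrays, 1 held untreated cells harvested 24 h after seeding (0 h) and 1 held cells kept for 45 days in cycles of 24 h at 0.2% oxygen and 48 h at 21% oxygen. The series states a single biological replicate per condition, so every difference below is a difference between 2 arrays without a replicate check.

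The deposited table holds log2 expression values for 53617 probe sets on each array. RMA and the oligo package are named in the submitters' processing notes, without versions. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a probe set on the log2 scale. Its settings, and the genome build behind the probe sets, were not given in the sources used here. The sorted values of the arrays differed by at most 0.13, so the distributions had been made nearly equal before deposition. Quantile normalization removes any overall rise or fall in RNA, and differences are therefore relative to the bulk of the genes. RMA compresses differences close to background. The number of arrays limits the precision, and no scanner files or detection calls were used here.

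Probe sets were named through the platform's annotation, and symbols were updated by Entrez ID through a gene table of assembly GRCh38.p14. Exactly 1 gene symbol was given for 23871 probe sets, several for 1842, and none here for 27904. Of the probe sets with 1 symbol, 22569 matched the gene table by Entrez ID, 733 by symbol only, and 569 were not in it and kept their old name. Probe sets of a gene were averaged, which gave 22395 genes, 632 of them with more than 1 probe set. No coordinates are printed because the build of the probe sets is not named. The gene table served for names, gene classes and the order of neighbouring genes.

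The level filter, the size threshold, the gene lists and their comparison with random lists were chosen before the data were examined. The olfactory receptor guide to background and the lower bounds described below were not named among those choices. A gene passed the level filter when the higher of its values on the arrays reached 5.24, the median over genes of the mean log2 value, and 11761 genes passed. A gene was called higher or lower by size alone when its log2 difference, 45 days of intermittent hypoxia minus untreated, was at least 1 in size (2-fold). No p-value was computed, because there are no residual degrees of freedom. The 358 measured olfactory receptor genes, which a breast cell line is not known to use, served as a guide to background: 95% of them had a mean log2 value below 4.54. Where the lower value of a gene lay under that level, its fold is also given as a lower bound computed against it. For each of 32 gene lists, the median difference of the measured members was set beside the medians of 10000 random lists of the same size, matched on mean level in 10 bins. The resulting percentile describes these arrays and is no test of the treatment. Random lists do not share regulation, whereas genes of a pathway do, so more than 5% of lists can fall outside the central 95% of random lists with no treatment effect. Of the list members, 85 entries had no probe set with a single symbol and were not analysed here.

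The genes named were the 12 protein-coding genes with the largest positive and the 12 with the largest negative difference among those passing the filter, without unnamed loci, histone or receptor-segment genes. The class of each gene came from the gene table, so pseudogenes and genes without a class there were also left out of these. Added to these were up to 4 members of each list where at least 1 member differed 1.5-fold or more, and a fixed set of genes of hypoxia, inflammation and metastasis. Further members that passed the 2-fold size threshold are named where a list's count is broken down, and members singled out in addition were chosen after their values were seen.

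The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. They were tested on simulated arrays of 22395 genes with the real levels and, as noise, the local robust spread of the real differences in windows of 501 genes of like level. Of 100 genes changed by 2 log2 units, 100% were called in the right direction, and of 100 genes changed by 1.5 log2 units, 91.0% were. That noise includes true differences of the real arrays, but it was drawn as normal, and a robust spread gives large differences little weight. Among real genes passing the filter, the SD was 0.56 and the robust SD 0.38. The noise also holds no measured variation between cultures. By size alone, 1.23% of unchanged simulated genes were called, which is not a rate of false calls for the real arrays. Among 200 unchanged lists of 25 genes, 3.50% fell outside the central 95% of random lists, and 100% of 50 lists shifted by 0.5 lay above it. The simulated noise was independent between genes, so these rates check the calculation and do not describe lists of genes that share regulation. Alternatives were another level filter or none, thresholds of 1.5-fold and 3-fold, centring on the array medians, removal of a lowess trend of the difference on the level (span 0.3), a further quantile normalization, the probe set with the highest level in place of the mean, other matching of random lists, and the mean in place of the median.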

Results

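The study asked how long-term intermittent hypoxia alters gene expression in inflammatory breast cancer cells, with attention, in its title, to metastasis-related genes and the transcription factor NF-κB. Its 2 arrays gave a single comparison, of SUM149PT cells after 45 days of cycling between 0.2% and 21% oxygen with untreated cells of the same line harvested at 0 h. No array of cells cultured for 45 days at constant oxygen was analysed here, and the labels do not say in which phase of the oxygen cycle the treated cells were harvested. Log2 values ran from 1.32 to 13.09 on the untreated array and from 1.26 to 13.10 on the hypoxia array, with medians of 4.34 and 4.35. Each condition had n = 1, so the values below carry no replicate error.

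Genes of the cell cycle were higher after intermittent hypoxia, the matrix protease gene MMP9 had the largest difference of all genes that passed the level filter, and the measured canonical targets of the hypoxia-inducible factors differed little. Across the genes that passed the filter, the arrays correlated with Pearson's r = 0.938, a value across genes, which are not independent replicates. Of these 11761 genes, 428 (3.64%) were at least 2-fold higher and 401 (3.41%) at least 2-fold lower in the hypoxia array, while 93.0% lay within 2-fold. These counts go by measured values: in 115 of the called genes the lower value lay below background, and in 35 of them (20 higher, 15 lower) the lower bound of the fold was under 2. A measured difference of 4-fold or more was seen in 34 genes upwards and 62 downwards, or 27 and 50 by bound, and of 8-fold or more in 6 and 14, or 4 and 8 by bound. By class, 391 of 10547 passing protein-coding genes were higher and 317 lower, against 13 and 34 of 511 long noncoding RNAs. Of 222 transcribed pseudogenes 4 were higher and 15 lower, and of 103 small nucleolar RNAs 0 and 12. Among these 12, 7 were SNORD116 copies from the same locus, which may share probes. The difference in balance between classes was not tested. Differences had a median of -0.058 and a robust SD of 0.38 on the log2 scale. Among the olfactory receptor genes, taken as background, 5 of 358 (1.40%) were 2-fold or more apart. For 107 genes with exactly 2 probe sets at or above the filter level, the probe sets' differences were a median of 0.28 apart. In 9 of these genes at least 1 probe set was 2-fold or more apart; both had the same sign in 7 of the 9 and both passed 2-fold in 0.

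**Figure D1:**
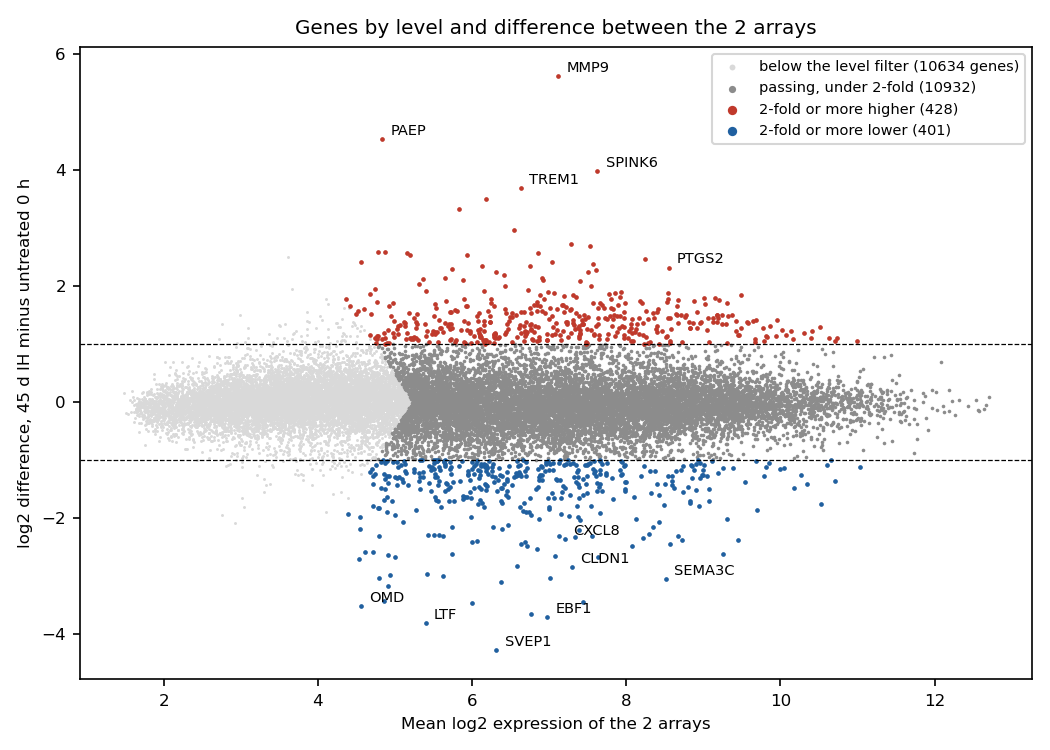
Log2 difference between the arrays (45 days of intermittent hypoxia minus untreated, vertical axis) against the mean log2 expression of the arrays (horizontal axis), 1 point per gene; light grey points are genes below the level filter, dark grey points pass it and lie within 2-fold, and dashed lines mark 2-fold. The 428 red points are the genes called higher and the 401 blue points those called lower, and MMP9 lies highest at 5.62.

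The 12 largest positive differences ran from MMP9 to SHC4. MMP9, which encodes the gelatinase matrix metalloproteinase 9, went from 4.30 in untreated cells to 9.92 after intermittent hypoxia, a log2 difference of 5.62. Its untreated value lay below the background level, so it was at least 41.7-fold higher. PAEP, the gene of the secreted lipocalin glycodelin, was at least 5.87-fold higher, with 2.57 and 7.09. SPINK6, a kallikrein inhibitor gene, was 15.7-fold higher (5.64 and 9.61), and TREM1, which encodes a receptor best known from myeloid cells, was 12.8-fold higher (4.79 and 8.47). OLFML3 was at least 10.5-fold and SERPINB10, a serpin gene, at least 7.70-fold higher. The metalloproteinase gene ADAM19 was 7.78-fold higher, the collagen VI chain COL6A3 6.55-fold, the ferritin receptor SCARA5 6.39-fold and the basement membrane nidogen NID2 5.93-fold. The sulfotransferase gene SULT1B1 and the adaptor gene SHC4 completed the 12 by measured difference, at least 2.89-fold and 3.71-fold higher. By bound, 10 of the 12 keep a place, and SULT1B1 and SHC4 give way to KPNA7 and TNC, a pair looked up after the values were seen.

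The largest negative difference was in SVEP1, the gene of a large extracellular adhesion protein, with 8.46 in untreated and 4.17 in treated cells, at least 15.1-fold lower. LTF, encoding the iron-binding protein lactoferrin, was at least 6.79-fold lower, and the transcription factor gene EBF1 was 13.2-fold lower (8.83 and 5.11). RGCC was 12.7-fold lower, SYT12 8.60-fold, the semaphorin gene SEMA3C 8.35-fold and PTX3, the gene of the innate immune protein pentraxin 3, 8.21-fold. Values of 9.17 and 5.71 were found for CYP4B1, a cytochrome P450 gene. The decoy receptor gene for interleukin 22, IL22RA2, was at least 9.13-fold lower. OMD was at least 3.43-fold, the cannabinoid receptor gene CNR1 at least 3.90-fold and EDIL3 at least 5.99-fold lower. By bound, 9 of these 12 keep a place, and OMD, CNR1 and EDIL3 give way to CLDN1, CHI3L1 and TNFSF10, also looked up after the values were seen.

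**Figure D2:**
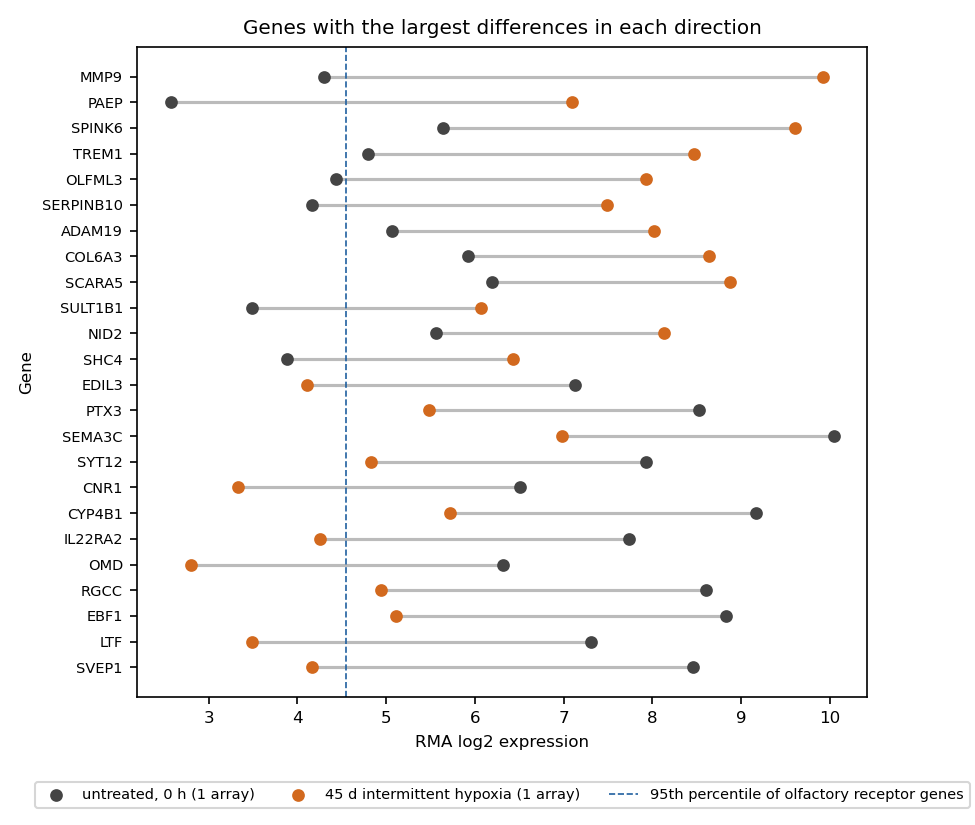
RMA log2 expression (horizontal axis) of the 12 genes with the largest positive and the 12 with the largest negative difference, 1 gene per line; grey points are the untreated array, orange points the array after 45 days of intermittent hypoxia, and the dashed line is the level of 4.54 that 95% of olfactory receptor genes stay under. MMP9 goes from 4.30 to 9.92, and SVEP1 from 8.46 to 4.17.

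Proliferation genes were higher as a group after intermittent hypoxia. All 38 measured members had a positive difference, from 0.44 for CDC20 to 1.83 for CDC6, and 28 were at least 2-fold higher. The list's median was 1.23, or 2.35-fold, above the medians of all 10000 matched random lists, whose central 95% ran from -0.17 to 0.079. CDC6, which licenses replication origins, went from 6.28 to 8.11. TYMS, encoding thymidylate synthase, went from 7.66 to 9.42, the mitotic kinase gene CDK1 from 6.82 to 8.51, and the S-phase transcription factor gene E2F1 from 7.35 to 9.05. The proliferation marker MKI67 was 2.32-fold and TOP2A 2.31-fold higher. DNA repair genes had a median of 0.57, also above all random lists, and 7 of 24 were at least 2-fold higher with 0 lower. These were POLQ (3.81-fold), RAD51AP1 (3.58-fold), EXO1 (3.49-fold), BLM (3.07-fold), RAD54L, FANCI and BRIP1, several of which act in replication-associated repair.

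Hypoxia-inducible factor (HIF) targets showed no member 2-fold apart. Of 25 targets outside glycolysis that passed the filter, 10 had positive and 15 negative differences, and the median over the 29 measured was -0.10 (21.5th percentile). STC2 and TMEM45A had differences of 0.75 and 0.65, ANKRD37 and the matrix cross-linking enzyme gene LOX of -0.67 and -0.62. VEGFA, which encodes the main angiogenic growth factor, had 7.82 and 7.36. CA9, BNIP3 and AK4 were not analysed here, nor was SLC16A3 of the glycolysis list, so the result covers the measured targets only. The 20 glycolysis genes had a median of 0.13 (96.7th percentile), and their largest differences were 0.72 for the hexokinase gene HK2, 0.55 for ENO2, -0.47 for TPI1 and 0.45 for PDK1. Among the factors themselves, HIF1A had 8.98 and 9.57, and the probe set with the higher level alone gave a difference of 0.28. EPAS1, encoding HIF-2α, had 11.26 and 10.92, and ARNT 9.35 and 8.94.

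The 24 measured genes of the NF-κB pathway and its feedback loop did not shift as a group, with a median of -0.043 at the 53.1st percentile. BIRC3 and SOD2 of this list were not analysed here. Of 22 members passing the filter, 1 was at least 2-fold lower: TNFAIP2, a gene induced by tumour necrosis factor, was 3.28-fold lower. The feedback inhibitor gene TNFAIP3 had a difference of 0.70, NFKBIZ of 0.65 and CD83 of -0.63. The subunit genes RELA and NFKB1 had differences of -0.19 and -0.31. These are RNA levels, and the activity of the NF-κB proteins was not measured on the arrays.

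Cytokines and inflammatory mediators differed in both directions. Of 23 passing members, 6 were higher and 5 lower by a measured 2-fold or more, and the median over the 33 measured was 0.12 (97.47th percentile), but 0.041 (83.3rd) over the passing members. PTGS2, encoding the prostaglandin synthase cyclooxygenase 2, was 4.97-fold higher (7.39 and 9.71). Also higher were IL1A (6.38 and 8.75), the interleukin 1 receptor antagonist gene IL1RN, LIF, CXCL10 and IL1B, the last from below background and so at least 1.79-fold. The chemokine gene CXCL8, encoding interleukin 8, was 5.17-fold lower (8.39 and 6.02), CXCL1 5.49-fold lower and the monocyte attractant gene CCL2 at least 5.69-fold lower. TNFSF10, the gene of the death ligand TRAIL, was 6.43-fold lower, and CSF1 was also lower. IL6 had 5.56 and 4.82.

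Matrix proteases and their regulators had a median of 0.19 (99.6th percentile), with 4 of 19 passing members at least 2-fold higher and 2 lower. Besides MMP9, the cathepsin gene CTSV was 3.96-fold higher, the plasminogen activator gene PLAT 3.43-fold, and MMP2 went from 4.95 to 6.22. The protease inhibitor gene TIMP3 was 3.15-fold and ADAMTS1 2.78-fold lower. MMP1 stayed below background, with 2.96 and 2.77. Among breast cancer metastasis genes, 3 of 20 were at least 2-fold higher and 4 lower, with a median of 0.11 (96.4th percentile), or 0.16 (98.9th, above the central 95%) over the passing members. TNC, encoding the matrix protein tenascin C, was 5.51-fold higher, with PTGS2 and MMP2 the others. CXCL1, ADAMTS1, LCN2 and CCN2 were lower, but the difference of CCN2 was -1.01, and -0.98 once the lowess trend was removed. The chemokine receptor gene CXCR4 had 6.84 and 7.60.

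Mesenchymal genes had a median of 0.16 (99.3rd percentile), but the 22 members passing the level filter alone had 0.096 (95.50th percentile), inside the central 95%. Of these, 3 were at least 2-fold higher and 0 lower: the microfibril gene FBN1 (5.09-fold), the intermediate filament gene VIM (2.71-fold) and the collagen gene COL6A1 (7.73 and 8.73), whose difference was 0.99 with the arrays centred on their medians, while THBS1 had a difference of -0.89. Fibroblast markers had a median of 0.084 (78.9th percentile), or 0.42 (94.80th) over the passing members, with 0 of 3 passing members 2-fold apart and differences of 0.83 for COL1A1, -0.45 for DCN and 0.42 for FAP. Epithelial junction genes had a median of -0.043 (48.8th percentile), which turned to 0.0067 with the lowess trend removed, and a mean of -0.20 (2.99th percentile). In that list the tight junction genes CLDN1 (7.25-fold) and TJP3 (2.97-fold) and the epithelial transcription factor gene ELF3 (2.26-fold) were lower, the desmoglein gene DSG3 was 2.15-fold higher, and CDH1, encoding E-cadherin, had 11.05 and 11.03.

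Basal markers had a median of -0.21 (4.71st percentile), with 4 of 14 at least 2-fold lower and 0 higher; their mean was -0.46 (0.14th percentile, below the central 95%). These were KRT15 (5.84-fold), the integrin gene ITGB4 (3.66-fold), KRT5 (2.69-fold) and CRYAB (2.33-fold). Luminal keratins and hormone receptor genes had a median of -0.058 (34.5th percentile), or -0.28 (4.04th) over the passing members, with KRT23 2.53-fold higher and KRT18 2.52-fold lower, and differences of -0.85 for MUC1 and -0.84 for KRT19. Squamous differentiation genes had a median of 0.15 (99.4th percentile), but 3 of 19 passing members were higher and 3 lower, and with those members alone the list lay at the 96.1st percentile. ZNF750 was at least 2.34-fold, KLK7 at least 2.65-fold and SERPINB3 2.43-fold higher, and KRT80 (2.66-fold), LCN2 (2.49-fold) and TGM1 were lower. Stem-like markers had a median of 0.25 (99.7th percentile), which became 0.14 (94.9th) with the highest probe set per gene. Of 8 passing members, only JAG1, encoding a Notch ligand, reached 2-fold, at 3.37-fold higher, while PROCR, CD44 and CD24 had differences of 0.56, 0.50 and -0.35. Genes associated with inflammatory breast cancer had a median of -0.062 (39.2nd percentile), with differences of -1.03 for RARRES1, or -0.98 with the lowess trend removed, and 0.96 for JAK2.

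Glucocorticoid targets were the only list below the central 95% of random lists, with a median of -0.32 (0.31st percentile), although by the mean of the members the list lay inside it, at the 2.95th percentile. ZBTB16 was 2.65-fold and GLUL 2.40-fold lower, MT2A was 2.42-fold higher, and CRISPLD2 had a difference of -0.81. Metallothioneins had a median of 0.18 (97.2nd percentile), with MT2A the only member 2-fold apart, and differences of -0.91 for MT1E, 0.77 for MT1F and -0.72 for SLC30A1. Growth factors had a median of 0.051 and a mean of -0.15 (83.4th percentile for the median), and a median of -0.090 over the passing members, with 3 of 19 lower and 0 higher: BMP4 (3.27-fold), FGF2 (2.56-fold) and DKK1 (2.19-fold), and FGFBP1 at -0.90. Immediate early genes had a median of 0.030 and a mean of -0.032 (83.9th percentile for the median), with FOSL1 2.55-fold and PHLDA1 2.03-fold higher, CCN2 lower, and SPRY2 at -0.94.

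By the median of all measured members, the stress, metabolic and immune lists that follow lay within the central 95% of random lists. p53 targets had a median of 0.14 (96.6th percentile), or 0.20 (98.6th, above it) over the passing members, with GADD45A 2.47-fold and PMAIP1 2.05-fold higher, TP53INP1 2.72-fold lower and CDKN1A at 0.84. Unfolded protein and integrated stress genes had a median of -0.052 (46.5th percentile), or 0.029 with the lowess trend removed, with PSAT1 2.10-fold higher, NUPR1 2.16-fold lower, CTH at -0.88 and SLC7A11 at 0.74. NRF2 targets had a median of -0.083 (24.4th percentile) and a mean of -0.17 (6.12th), with ABCC3 2.76-fold and AKR1B10 at least 1.74-fold lower, and AKR1C2 and TXNRD1 at -0.95 and -0.87. Cholesterol genes had a median of 0.13 (95.4th percentile) and no member 2-fold apart, the largest being INSIG1 at 0.87, followed by EBP, ACAT2 and MSMO1 at 0.49, 0.43 and 0.42. The fatty acid list had a median of -0.0052 (66.02nd percentile), or 0.077 with the lowess trend removed and 0.037 after quantile normalization. In it LPIN1 was 4.96-fold lower, and PPARG, DGAT2 and ACSL1 had differences of 0.95 (1.03 with the lowess trend removed), 0.69 and -0.64. Interferon-stimulated genes had a median of 0.10 (95.04th percentile) and a mean of 0.17 (98.8th, above it), with OAS3 2.87-fold higher and UBE2L6, IFIH1 and DDX60 at 0.97 (1.03 with the lowess trend removed), 0.88 and 0.87. Antigen presentation genes had a median of 0.055 (77.3rd percentile), or 0.16 (93.2nd) over the passing members, with TAP2, TAP1, CD74 and NLRC5 at 0.94 (1.03 with the lowess trend removed), 0.81, 0.41 and -0.41.

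Ribosomal, respiratory chain, reference, leukocyte and endothelial lists also lay within the central 95% of random lists, by the median with matching on level. Ribosomal proteins had a median of -0.17 (9.36th percentile), with RPLP1, RPL10A, RPS24 and RPL6 at 0.78, -0.58, -0.51 and 0.41. Mitochondrial respiratory chain subunits had -0.17 (4.54th percentile, or 2.41st without matching on level) and no member 2-fold apart. Of their 30 passing members, 24 had negative and 6 positive differences. Common reference genes had 0.091 (89.1st percentile). Among these, ACTB, encoding β-actin, was 2.42-fold lower, and HPRT1, GUSB and TBP had differences of 0.62, 0.38 and 0.25. Markers of leukocytes (median 0.16, 96.9th percentile, 4 of 15 passing the filter) and endothelial cells (0.16, 90.0th percentile, 1 of 11 passing) had no member 2-fold apart among those passing. Of the 32 lists, 6 lay above and 1 below the central 95% of random lists, where chance alone would put 1.6 outside, and 41 genes belonged to more than 1 list. The 6 were proliferation, DNA repair, stem-like, protease, squamous and mesenchymal genes, and the first pair stood apart from the rest in size.

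**Figure D3:**
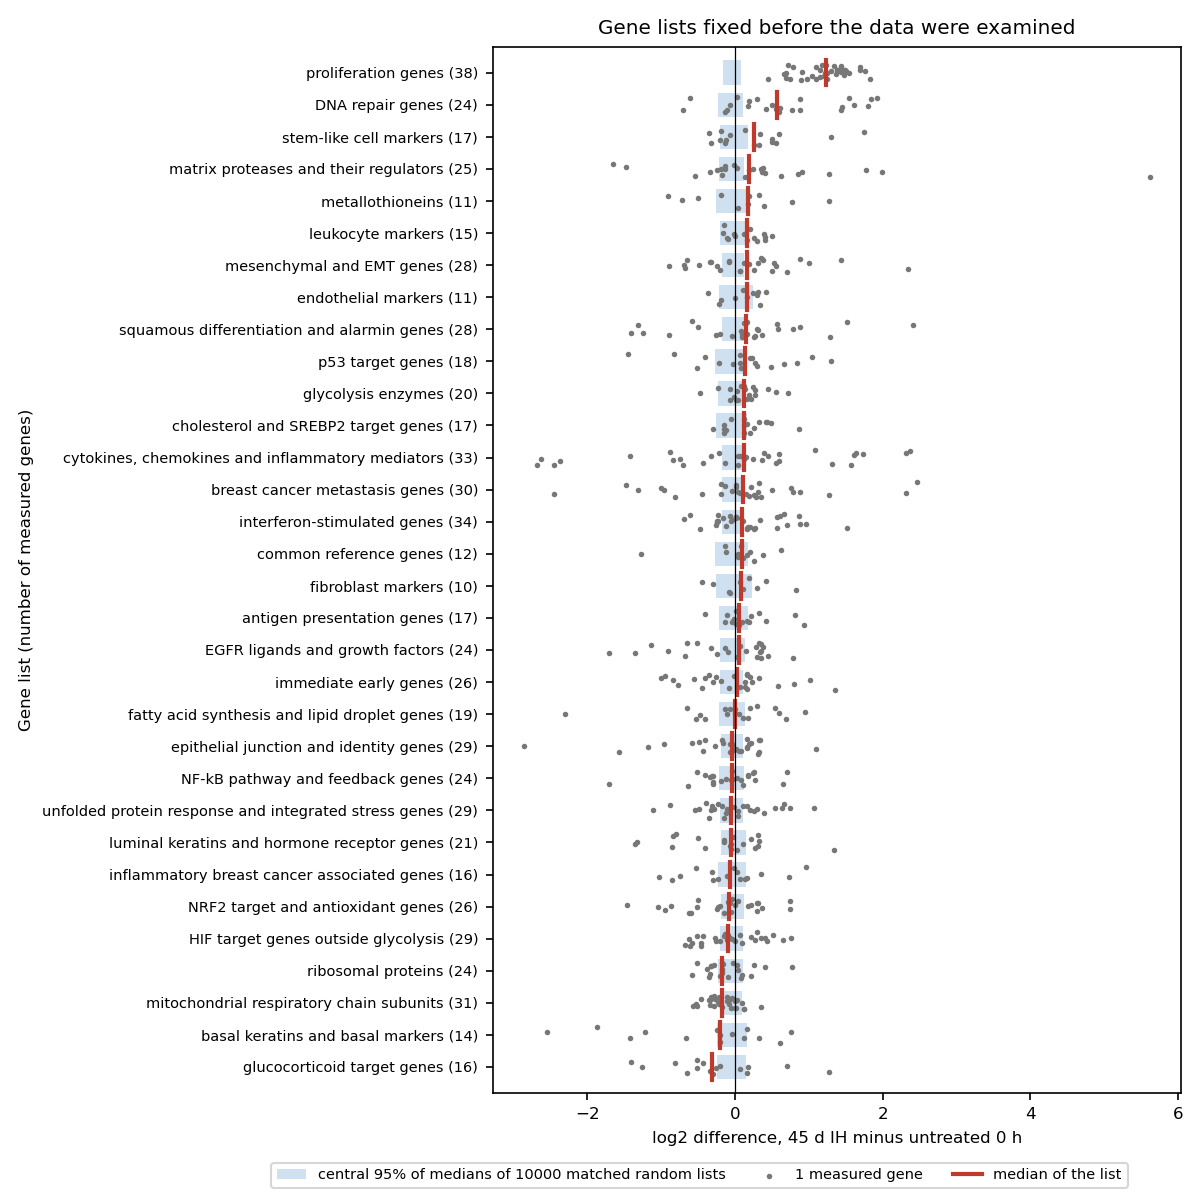
Log2 difference (45 days of intermittent hypoxia minus untreated, horizontal axis) of the measured genes of each list, 1 point per gene; the red bar is the list's median and the blue band the central 95% of medians of 10000 random lists matched on level. Proliferation genes (median 1.23) and DNA repair genes (0.57) lie clear of their bands, and glucocorticoid targets (-0.32) lie below theirs.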

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

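Outside the gene comparison, 377 of 7953 probe sets that carry no or several gene symbols and pass the level filter were at least 2-fold higher in the hypoxia array than in the untreated array (4.74%), and 350 were at least 2-fold lower (4.40%). They drew attention because the named-gene comparison does not use them. Of the 377, 348 carry no symbol here and 29 carry several. With 1 array per condition, no sample could stand apart from its group.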

How the results depend on the processing

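Counts, list medians and named genes were each recomputed under the alternatives that apply to them. A pool of protein-coding genes for the random lists and centring of the named genes were chosen after seeing the data; the first moved no list across the central 95%, and the second took COL6A1 to 0.99. No paired analysis was possible because each condition has a single array. The counts of 428 higher and 401 lower genes became 250 and 196 with the filter at the 75th percentile, 1050 and 1263 at 1.5-fold, and 104 and 124 at 3-fold. Requiring also 3 local robust SDs left 257 lower genes. The other 13 of 20 recounts stayed within 1.5 times, among them the 348 higher genes under that requirement. Rescaling moved the median of all genes by at most 0.03, and the share of called genes that were higher, 51.6%, ranged from 45.4% to 57.9% over the 10 alternatives. The medians of proliferation, DNA repair and protease genes stayed above the central 95% of random lists under all alternatives run for them. With members passing the level filter only, medians were 0.041 for cytokines, 0.16 for metastasis genes (now above the central 95%, as at the olfactory receptor level, 0.16), 0.096 for mesenchymal and 0.16 for squamous genes (both now inside), -0.28 for luminal, 0.16 for antigen presentation, -0.090 for growth factor and 0.42 for fibroblast genes, and 0.20 for p53 targets (now above, as at the olfactory receptor level, 0.20); endothelial markers gave no value there, with fewer than 3 members left. At the olfactory receptor level, mesenchymal genes had 0.13 and squamous genes 0.16, both inside, luminal genes -0.15, and interferon genes 0.17, above. The cytokine list lay above the central 95% with the lowess trend removed (0.17), after quantile normalization again (0.16), and at its unaltered median of 0.12 with the highest probe set, 20 bins or no matching. Without matching, interferon genes (0.10) lay above it and respiratory chain genes (-0.17) below. The highest probe set took stem-like markers inside (0.14), and the lowess fit turned the stress list from -0.052 to 0.029. By the mean, cytokines had 0.043, epithelial genes -0.20, basal genes -0.46 (now below the central 95%), luminal genes -0.17, squamous genes 0.14 (inside), NRF2 targets -0.17, interferon genes 0.17 (above), growth factors -0.15 and glucocorticoid targets -0.27 (inside). Of 576 recomputed differences of the 144 named genes, none reversed a call and 566 kept their side of 2-fold and moved by less than the local spread. The cause of these changes was not tested. With 1 array per condition, no alternative can stand in for biological variation, and values below the background level have no order.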

Other observations

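The tests on symbol families, on fibroblast markers, on days in culture, on the protein-coding and other non-coding genes of the shifted window and on other small nucleolar RNAs were chosen only after the results they bear on had been seen. Of 161 families of at least 8 protein-coding genes that share a symbol stem before a digit and pass the level filter, 8 had medians above and 10 below the central 95% of matched random lists, where chance would put 8.05 outside. Another 3 families, CENP, SERPIN and ACS, were picked by hand after values had been seen, so their place among random lists is no test. Of the families outside, 0 changed sign under centring, lowess removal or quantile normalization. Besides the centromere protein genes (CENP, 18 genes, median 1.09), kinesins (KIF, 28 genes, 0.61) and MCM genes (10 genes, 0.84), the genes with SERPIN symbols had a median of 0.86, with 4 of 10 at least 2-fold higher. These were SERPINB10, SERPINB7 (difference 1.62), SERPINB3 and SERPINA1 (1.07). The GALNT glycosyltransferases had a median of 0.32, with 3 of 12 higher, GALNT12 by 1.31, GALNT15 by 1.26 and GALNT14 by 1.22.

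Acyl-CoA synthetases of the ACS group had a median of -0.90, with 4 of 8 at least 2-fold lower and 0 higher. ACSS1 and ACSS3 were below background in the hypoxia array, at least 3.03-fold and 2.16-fold lower, and the differences of ACSL5 and ACSF2 were -1.99 and -1.16. Cytochrome P450 genes had a median of -0.37, with 5 of 16 lower by a measured 2-fold or more, among them CYP4B1, CYP7B1 (-2.12) and CYP4F22 (-1.71). Intraflagellar transport genes, which build cilia, had a median of -0.43 over 18 genes, and IFT122 (-1.29) was the only member 2-fold lower. Zinc finger genes with ZNF symbols had a median of -0.19 over 320 genes, with 6 higher and 8 lower.

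The higher proliferation genes may reflect a larger share of cells in S phase, as a hypothesis. Replication-dependent histone genes, transcribed mostly in that phase, had a median of 0.68 over the 17 that pass the filter, with 3 at least 2-fold higher and 0 lower, but single genes ran from -0.98 for H2BC5 to 1.57 for H1-5. A trend of the difference with signal level is argued against as the whole cause, since the proliferation median was 1.28 once that trend was removed. Hypoxia, 45 days of culture and the 24 h between seeding and harvest of the untreated cells cannot be told apart, because 0 arrays of cells cultured for 45 days without hypoxia were analysed here.

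MMP9, TREM1 and matrix genes were among the largest positive differences. Gain of the chromosome segment that holds MMP9 is argued against by its 20 nearest genes passing the filter, with a median of -0.12 and a range from -0.79 to 0.59. RNA of neutrophils or monocytes is argued against by 22 myeloid markers with a median of 0.062 and 0 at least 2-fold higher, and by LYZ at 4.38 and SRGN at 3.88 in the hypoxia array; 6 of the 22 are also in other lists, and 5 reached the filter level in untreated cells. RNA of fibroblasts is argued against by abundant fibroblast transcripts, singled out after the values were seen, that stayed below background in the hypoxia array. These were COL1A2 and LUM, both at 3.45, and POSTN at 3.02. COL3A1 and PDGFRA had no probe set with a single symbol. The median over 10 markers was 0.084, but 0.42 over the 3 passing the filter, COL1A1, DCN and FAP, which untreated cells also express. Of the 10, 3 are in other lists. Regulation by the treatment stays open and untested, as does outgrowth of a subclone over 45 days.

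A run of neighbouring genes on chromosome 15 was lower in the hypoxia array. Gain or loss of chromosome segments was the explanation tested as planned, and its prediction was met: the median of the window of 30 genes with the largest shift lay 0.63 from that of all genes, against at most 0.49 in 200 shuffled gene orders. After the window had been seen, its 9 protein-coding genes were found to have a median of -0.055, from -0.32 to 0.24. These values argue against loss of the whole segment, so the reading changed with a test added later. They cannot speak to a loss limited to the SNORD116 stretch, where the window holds no protein-coding gene. Nor can they decide, in an imprinted region, on loss of a single parental copy in part of the cells. The shift came from 14 SNORD116 small nucleolar RNAs of the imprinted Prader-Willi region, the long noncoding RNA PWAR6 (-1.50) and pseudogenes such as HERC2P2 (-1.18). The SNORD116 copies had a median of -1.02, from -1.61 to -0.57, and 7 were at least 2-fold lower. They come from the same locus and may share probes, so they were not taken as independent. Their untreated levels ran from 5.33 (SNORD116-25) to 11.56 (SNORD116-15), so they did not all read the same signal. Lower recovery of small RNA is argued against for the window's 7 pseudogenes and long noncoding RNAs, which it would not lower. Their median was -0.75, at percentile 0.39 among random sets of these classes. The window was picked for its shift, and over the 15 windows holding all SNORD116 copies this median ran from -0.92 to -0.34. For SNORD116, lower recovery cannot be told apart from a change at this locus. All 14 copies lay below the median of 89 other small nucleolar RNAs, but 4 of the 89 were as low as the SNORD116 median. The 89 had a median of -0.26 and the 30 C/D box ones of like length -0.38, between the values that would decide it. The gap of -0.76 exceeded the robust SD of the 89, 0.57, but it sets copies that may share probes against single genes.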
